A study of Homo sapiens with 13 samples.

How the data were processed

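RNA of MCF10A cells, an established non-tumorigenic human breast epithelial line, was measured on 13 Affymetrix HG-U133 Plus 2 expression arrays. Per the labels' protocols, the cells grew in medium with 5% horse serum, 20 ng/ml EGF, 10 µg/ml insulin and 0.5 µg/ml hydrocortisone. Monolayers at 90 to 95% confluency supplied the cells that were seeded on permeable supports with 0.4 µm pores, where the medium of both chambers was changed every 24 hours. Transepithelial electrical resistance was followed daily, and RNA was taken at stages the labels call base, midpoint and plateau. The resistance values and culture days of these stages are not given in the sources used here. Total RNA with an integrity number above 7.0 was amplified once and labelled with biotin, per the labels' protocols.

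The values used were the log2 expression values that the authors deposited, 1 for each of 54675 probe sets on each array. RMA and limma are named in the submitters' processing notes, without versions, parameters or roles, and whether other arrays were normalized in the same run is not given in the sources used here. The base of the logarithm is not stated either. It was taken as 2 because the values lay between 1.77 and 15.0 (log2), the range of a 16-bit scanner, so every fold given here rests on that reading. The sorted values of the arrays lay at most 0.0871 (log2) from their mean over arrays, so they had been brought to nearly the same distribution. No pair of arrays held identical values, and the smallest median absolute difference between any 2 arrays was 0.0904 (log2). The number of arrays limits the precision. Deposited values carry no detection calls, so a background level was set at the 95th percentile of 82 olfactory receptor genes, 6.17 ± 0.0836 (log2, SD over 13 arrays), and 7652 genes had every group mean at or under it.

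Probe sets were named from the platform annotation supplied with the data. A single gene was named for 41097 probe sets, several genes for 1801, and none for 11777. None of the 62 control probe sets was the probe set tested for a gene. Symbols of 41043 probe sets were taken through their gene identifiers from a RefSeq gene table of assembly GRCh38.p14, whether or not the symbol changed. No coordinates were used from that table. For each of 19775 genes the probe set with the highest mean over all arrays was tested, and 10523 genes had more than 1. Probe sets with several genes or no name entered no comparison.

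Groups came from the labels, with 3 monolayer, 3 base, 3 midpoint and 4 plateau arrays. The comparisons, tests, gene lists, named-gene rule and other settings tried were fixed before the data were examined. Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), in 1 model of all 4 groups with no covariate, and a gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. An absolute log2 change of 1 was used only for counts of larger changes. The main comparisons were base against monolayer, midpoint against base, plateau against midpoint and plateau against monolayer, with counts and list tests only for midpoint against monolayer and plateau against base. All changes are log2 differences, the later stage minus the earlier, with the standard error (SE) of the fit. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

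The 26 gene lists held 556 genes, of which 517 were measured. They covered tight junctions, polarity complexes, adherens junctions, desmosomes, hemidesmosomes with basement membrane, DNA replication (G1/S), mitosis (G2/M), cornified envelope, secreted defence proteins, basal and myoepithelial markers, luminal markers, milk genes, mesenchymal markers, cholesterol synthesis, hypoxia and glycolysis, interferon response, NF-kappaB and inflammation, EGFR and MAPK response, YAP targets, p53 targets, ER stress and amino acid response, ion and water transport, oxidative phosphorylation, and endothelial, leukocyte and adipocyte markers. Each was tested with limma's camera at a preset correlation of 0.01 between genes, which asks whether a list shifted relative to all other genes. Its adjusted p ran over all 156 tests. The same test with an estimated correlation (median 0.069) and the rotation test fry were run beside it. Members were also counted with p-values adjusted over the list alone.

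Genes were named by a fixed rule in each main comparison. It took the 8 largest rises and the 8 largest falls among changed genes whose arrays did not overlap between the groups, leaving out provisional symbols. It then took up to 4 changed members with the largest change from each list that passed camera, and always 10 panel genes (CLDN1, CLDN4, OCLN, TJP1, CDH1, KRT14, KRT18, MKI67, VIM and IVL). RNA quality was measured as the difference between 3' and 5' control probe sets of ACTB and GAPDH, with exact two-sided permutation tests over the groups. A difference for the bacterial poly-A spike transcript dap and a ribosomal RNA signal were added after the data had been seen.

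The tests were tried on simulated values with known changes, 50 genes of each size among 19775. In base against monolayer, absolute changes of 0.25, 0.5, 1 and 2 (log2) were recovered for 14%, 66%, 100% and 100% of the genes, with 6 false calls among 150. In midpoint against base the shares were 20%, 74%, 100% and 100%, with 17 false calls among 167. In plateau against midpoint they were 4%, 66%, 96% and 100%, with 7 false calls among 145. In plateau against monolayer they were 14%, 70%, 100% and 100%, with 4 false calls among 149. A simulated list of 30 genes shifted by 0.25 gave camera p-values between 1.07e-36 and 5.66e-20 over these comparisons, and an unshifted list between 0.237 and 0.925. The simulated genes varied independently of each other, whereas the estimated correlation reached 0.567 in the mitosis list. The simulation therefore cannot show how camera at the preset correlation behaves on lists of correlated genes. Few genes were changed in each simulation, whereas 41.4% of the genes changed in the real base against monolayer comparison. The adjusted p depends on that share, and real changes as small as 0.0856 (log2) passed there. The recovered shares therefore do not carry over to the comparisons against the monolayer.

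The other settings tried were the replicate number as a block, a filter at the median gene, the mean of a gene's probe sets or every probe set, only the groups compared, no trend in the prior variance, array weights, median centring, cyclic loess, quantile normalization, a minimum change, and leaving out each array in turn. Covariates for the ACTB and spike differences, a recount of list members and quality measures without base replicate 2, and tests of gene families and 4 further gene lists were chosen after seeing the data. Python 3.11.15 with matplotlib 3.10.9 drew the figures.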

Results

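Gene expression was measured on 13 arrays of MCF10A cells, a non-tumorigenic human breast epithelial line. Of these, 3 came from cells grown as ordinary monolayers, which served as the control. The others came from cells on permeable supports at stages of transepithelial electrical resistance, the resistance of a cell sheet to current and a measure of how tightly it is sealed. There were 3 arrays at base, 3 at midpoint and 4 at plateau. By its title, the study followed expression through differentiation on the supports. The monolayer differs from the supports in substrate and culture time as well as in stage, and these differences cannot be told apart here.

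Arrays of the same group correlated at 0.995 or higher over the 19775 genes, and monolayer arrays correlated with the others at 0.953 to 0.970. The first principal component held 80.3% of the variance and parted the monolayers from all arrays on supports, while the second held 5.81% and ran from base through midpoint to plateau. A limma F test found that 9222 of 19775 genes differed among the 4 groups. Base replicate 2 lay apart from the other base arrays, with the lowest estimated array weight (0.292) and the smallest 3' minus 5' difference of ACTB (0.617, log2). The group means of that difference spanned 0.216 (log2, exact permutation p = 0.924) and those of GAPDH spanned 0.219 (exact permutation p = 0.148, adjusted p = 0.295).

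**Figure D1:**
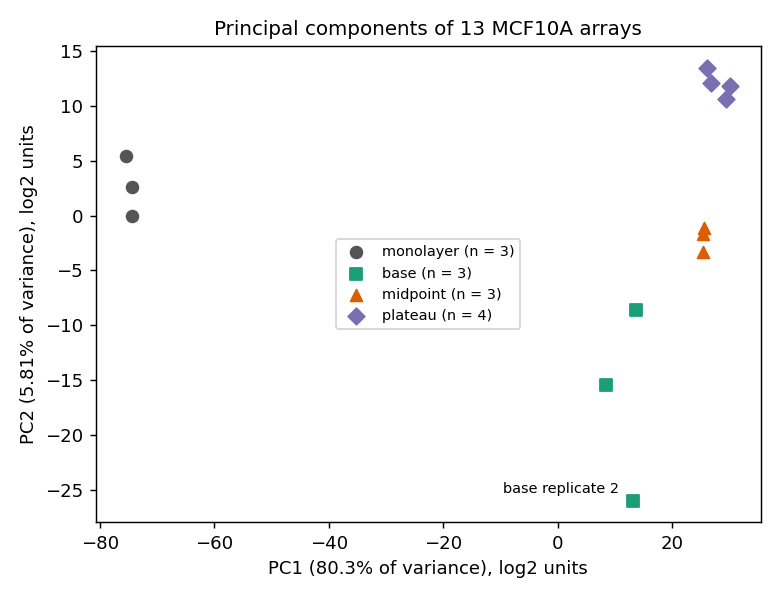
Each point is 1 array, placed by its first (horizontal, 80.3% of the variance) and second (vertical, 5.81%) principal component of the log2 levels of 19775 genes, with 3 monolayer, 3 base, 3 midpoint and 4 plateau arrays. The monolayers lie between -75.5 and -74.4 on the horizontal axis and all other arrays at 8.45 or above, and base replicate 2 has the lowest vertical position, at -26.0.

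The base against monolayer comparison asks what differed between ordinary monolayers and the base stage on the supports. Changes are given as log2 change ± SE, 3 arrays against 3. KRT4 and KRT13, keratins of the suprabasal layers of mucosal epithelia, rose by 7.05 ± 0.09 and 6.11 ± 0.077. GABRP, the pi subunit of the GABA-A receptor, rose by 7.85 ± 0.12 and the secreted glycoprotein gene OLFM4 by 6.61 ± 0.20. KRT4, GABRP and OLFM4 all started below background, so the sizes of these rises are uncertain. Cell-cycle genes fell together, among them the replication factor gene MCM10 by 2.86 ± 0.18 and the proliferation marker MKI67 by 1.99 ± 0.15.

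The other large rises were KRTDAP (6.18 ± 0.26), a gene of differentiating keratinocytes, A2ML1 (5.78 ± 0.15), a protease inhibitor, KLK7 (5.68 ± 0.084), a protease that loosens shed keratinocytes, and PLA2G2A (5.65 ± 0.14), a secreted phospholipase. The largest falls were those of THBS1 (thrombospondin), at -3.78 ± 0.15, and ETV5, an ETS factor downstream of MAPK signalling, at -3.45 ± 0.14. ALOX5AP, which serves leukotriene synthesis, fell by 3.42 ± 0.10, and the collagen gene COL8A1 by 3.34 ± 0.13, though another probe set of COL8A1 gave 0.061 (adjusted p = 0.731). SHISA2, IL7R, SPC25 and PLAC8 fell too, with changes between -3.35 and -3.01. The adjusted p of these 16 genes lay between 8.97e-21 and 1.64e-12. Monolayer means of GABRP (4.92), KRT4 (5.60), OLFM4 (2.97), KRTDAP (4.95) and A2ML1 (3.93) were below the background level of 6.17 (log2), as were the base means of SHISA2 (4.41) and IL7R (5.18). These changes, and the order of genes by size, therefore rest partly on background signal. The same holds for CLDN8, SCNN1B, EGLN3 and IFI44 below, whose monolayer means lay under it.

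In the cornified envelope list, 23 of 36 measured members rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 7.27e-13; adjusted p = 0.00588 with an estimated correlation). IVL, a cross-linked precursor of the envelope, rose from 8.18 ± 0.094 to 11.2 ± 0.21 (level, mean ± SD). In the desmosome list, 9 of 15 rose and 1 fell, again the same adjusted over the list alone (adjusted p = 1.16e-06; adjusted p = 0.0256 with an estimated correlation). The desmosomal cadherins DSC2, DSG3 and DSC3 rose by 2.58 ± 0.068, 2.38 ± 0.072 and 1.99 ± 0.072.

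Of the tight junction genes, 14 of 25 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.00168; adjusted p = 0.0643 with an estimated correlation). The claudins, which form the strands, included CLDN8 (3.67 ± 0.29), CLDN4 (1.94 ± 0.083), CLDN7 (1.39 ± 0.092) and CLDN1 (0.86 ± 0.088), and occludin (OCLN) rose by 1.72 ± 0.092. The scaffold gene TJP1 did not pass, at -0.05 ± 0.05 (adjusted p = 0.495). In the adherens junction list 6 of 11 rose and 3 fell, or 7 and 3 adjusted over the list alone (adjusted p = 0.0218; adjusted p = 0.308 with an estimated correlation), with CDH1 (E-cadherin) up by 1.14 ± 0.058, JUP (plakoglobin) up by 1.88 ± 0.10 and NECTIN3 down, at -0.86 ± 0.11. Secreted defence genes rose in 7 of 15 cases and fell in 0, also adjusted over the list alone (adjusted p = 0.000242; adjusted p = 0.0643 with an estimated correlation), with the protease inhibitor gene PI3 at 4.49 ± 0.094 and lipocalin (LCN2) at 2.98 ± 0.14. Ion and water transport genes rose in 11 of 24 cases and fell in 4, or 12 and 4 adjusted over the list alone (adjusted p = 0.00513; adjusted p = 0.0643 with an estimated correlation). Among them carbonic anhydrase CA2 rose by 2.81 ± 0.082 and the sodium channel subunit SCNN1B by 2.59 ± 0.13.

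Of the luminal markers, 10 of 24 rose and 3 fell, or 10 and 5 adjusted over the list alone (adjusted p = 0.00661; adjusted p = 0.0831 with an estimated correlation). The mucin MUC1 rose by 3.54 ± 0.082 and CD24 by 3.45 ± 0.044, while the luminal keratin KRT18 fell by 1.32 ± 0.10. The basal keratin KRT14 rose by 3.58 ± 0.18, and VIM (vimentin) did not pass, at -0.07 ± 0.13 (adjusted p = 0.721). In the hypoxia and glycolysis list 19 of 23 rose and 1 fell, the same adjusted over the list alone (adjusted p = 2.74e-09; adjusted p = 0.172 with an estimated correlation), led by the prolyl hydroxylase EGLN3 (3.61 ± 0.15) and NDRG1 (2.66 ± 0.06). Interferon-stimulated genes rose in 14 of 26 cases and fell in 3, the same adjusted over the list alone (adjusted p = 0.000812; adjusted p = 0.294 with an estimated correlation), with SAMD9 at 2.47 ± 0.064 and IFI44 at 1.99 ± 0.12.

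Every measured gene of the DNA replication list (29 of 29) and of the mitosis list (30 of 30) fell, also when adjusted over the list alone, with median changes of -1.90 and -1.77. Their adjusted p-values were 3.08e-23 and 1.88e-22, or adjusted p = 0.0643 and 0.0834 with an estimated correlation. Ribonucleotide reductase RRM2 fell by 2.38 ± 0.097, the anaphase activator CDC20 by 2.34 ± 0.18 and the kinase AURKB by 2.28 ± 0.10. Cholesterol synthesis genes fell in 12 of 18 cases and rose in 0, with 13 falls adjusted over the list alone (adjusted p = 9.09e-05; adjusted p = 0.271 with an estimated correlation), among them ACAT2 by 1.44 ± 0.12 and the sterol sensor INSIG1 by 1.41 ± 0.09. In the EGFR and MAPK list 13 of 23 fell and 6 rose, or 14 and 6 adjusted over the list alone (adjusted p = 0.00985; adjusted p = 0.172 with an estimated correlation), with the ligand EREG at -2.57 ± 0.23 and FOS, an immediate-early gene, at 2.22 ± 0.19. Oxidative phosphorylation genes fell in 13 of 26 cases and rose in 5, or 14 and 5 adjusted over the list alone (adjusted p = 0.037; adjusted p = 0.269 with an estimated correlation). CYC1, a subunit of the respiratory chain, fell by 0.50 ± 0.069, and this list did not pass without base replicate 3 (adjusted p = 0.068) or monolayer replicate 3 (adjusted p = 0.0552).

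Of the lists that did not pass in this comparison, counts of rises and falls were 7 and 1 of 19 polarity genes (adjusted p = 0.111), 8 and 5 of 16 hemidesmosome genes (0.685), 7 and 5 of 16 basal markers (0.0595), 1 and 1 of 8 milk genes (1), 11 and 6 of 24 mesenchymal markers (0.0978), 6 and 10 of 23 NF-kappaB genes (0.759), 7 and 9 of 21 YAP targets (0.563), 4 and 7 of 17 p53 targets (0.755) and 6 and 11 of 20 ER stress genes (0.0848). The basal list passed without base replicate 1 (adjusted p = 0.0299) or monolayer replicate 3 (adjusted p = 0.0366), and the ER stress list without base replicate 2 (adjusted p = 0.0306). For the hemidesmosome, milk, NF-kappaB and p53 lists the median, mean and test differed in sign. Markers of other cell types did not pass, with 0 rises and 1 fall of 10 endothelial, 1 and 2 of 10 leukocyte and 3 and 1 of 8 adipocyte genes (adjusted p = 0.586, 0.587 and 0.4). A list of nuclear-retained RNAs chosen after the data had been seen moved with these groups, with 10 of 14 members higher, 0 lower and a median of 0.62 (camera p = 1.52e-06; p = 0.00166 with an estimated correlation).

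In all, 8194 of 19775 genes changed between monolayer and base, 4000 higher and 4194 lower, and 1650 of them by at least 1 (log2), 901 higher and 749 lower. Centring each array on its median, which moved the median change of all genes by up to 0.135 (log2) among the comparisons, gave 3245 higher and 5616 lower. Without base replicate 2 the hypoxia and glycolysis list had 17 rises and 3 falls, the oxidative phosphorylation list 3 rises and 13 falls and the luminal list 10 rises and 5 falls.

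**Figure D2:**
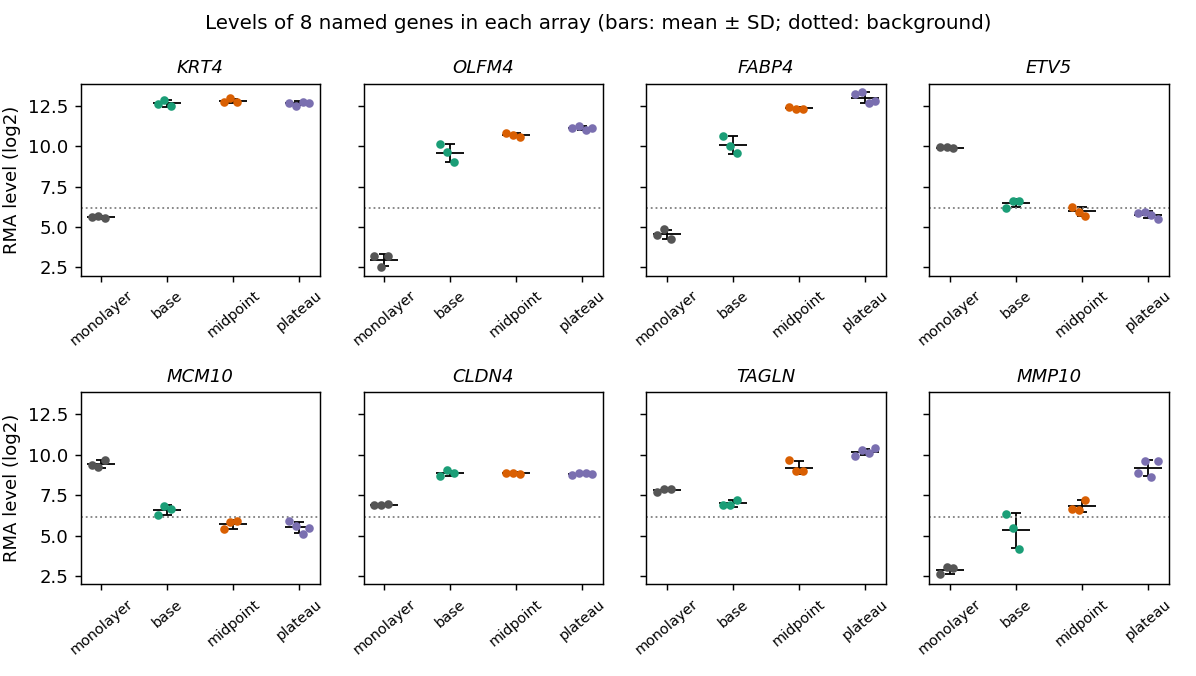
Each panel shows 1 gene, with the RMA level (log2) of every array as a point for monolayer (n = 3), base (n = 3), midpoint (n = 3) and plateau (n = 4), black bars for the mean ± SD and a dotted line at the background level of 6.17. KRT4 stood at 5.60 in the monolayer and 12.6 at base, CLDN4 at 6.92 and 8.86, and MMP10, below background in the monolayer and at base, reached 6.82 ± 0.36 at midpoint and 9.18 ± 0.52 at plateau.

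The midpoint against base comparison covers the first step along the resistance stages. With 3 arrays in each group, CLCA4, a regulator of chloride conductance, rose by 2.66 ± 0.28, the antimicrobial peptide gene S100A7 by 2.38 ± 0.21, the fatty acid carrier FABP4 by 2.27 ± 0.20 and the actin-binding protein gene TAGLN by 2.21 ± 0.15. AOC1, an amine oxidase, rose by 2.26 ± 0.20, and DAPL1, GPR15LG and TCN1, which carries vitamin B12, rose by 1.67 ± 0.18, 1.67 ± 0.17 and 1.62 ± 0.17. The largest falls were those of UGT8, which makes galactosylceramide (-1.54 ± 0.14), the protease inhibitor SERPINA1 (-1.44 ± 0.19), the glucose transporter SLC2A3 (-1.41 ± 0.22) and the secretoglobin SCGB1A1 (-1.31 ± 0.13). FBN2 (fibrillin), BEST2, MFSD2A and IL27RA fell too, with changes between -1.26 and -1.15. The adjusted p of these 16 genes lay between 1.35e-07 and 0.00397. UGT8 lay below the background level of 6.17 in both groups, as did CLCA4, DAPL1 and GPR15LG at base and BEST2 at midpoint, so the sizes and order of these changes rest partly on background signal. Another probe set of SERPINA1 gave 0.145 and one of FBN2 gave 0.068 (adjusted p = 0.68 and 0.903). FABP4 is also an adipocyte marker, but 1 of the 8 adipocyte genes rose and that list did not pass (adjusted p = 0.749), with ADIPOQ at 2.72 and PLIN1 at 6.33 (log2) at plateau.

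Cell-cycle genes fell further. In the mitosis list 27 of 30 fell, or 30 adjusted over the list alone, and in the replication list 19 of 29 fell, or 24 adjusted over the list alone, with 0 rises in either. Their median changes were -0.58 and -0.39 (adjusted p = 4.48e-33 and 1.93e-23; adjusted p = 0.0643 for both with an estimated correlation). CDC20 fell by 0.91 ± 0.18, CCNB1 (cyclin B1) by 0.77 ± 0.10 and RRM2 by 0.91 ± 0.097. Cholesterol synthesis genes fell in 11 of 18 cases, or 13 adjusted over the list alone (adjusted p = 8.3e-15; adjusted p = 0.0643 with an estimated correlation), among them FDPS by 0.82 ± 0.10 and HMGCS1 by 0.72 ± 0.12, enzymes of the mevalonate route. In the NF-kappaB list 10 of 23 fell and 0 rose, with 12 falls adjusted over the list alone (adjusted p = 6.53e-11; adjusted p = 0.0625 with an estimated correlation). The chemokines CXCL2 and CXCL1 fell by 1.11 ± 0.15 and 1.04 ± 0.18, and TNFAIP3, a feedback inhibitor of the pathway, fell by 0.78 ± 0.072. Of the EGFR and MAPK genes 5 of 23 fell and 0 rose, with 13 falls adjusted over the list alone (adjusted p = 1.65e-07; adjusted p = 0.0489 with an estimated correlation), and the phosphatase DUSP6 fell by 0.62 ± 0.15.

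Oxidative phosphorylation genes fell in 4 of 26 cases and rose in 0, with 10 falls adjusted over the list alone (adjusted p = 0.000149; adjusted p = 0.0756 with an estimated correlation), the changes of CYC1, SDHD, UQCRC2 and ATP5F1A lying between -0.28 and -0.21, though another probe set of ATP5F1A gave 0.05 (adjusted p = 0.929). The hypoxia and glycolysis list shifted lower with a median of -0.088, although 0 of 23 members passed over all genes or adjusted over the list alone (adjusted p = 0.000393; adjusted p = 0.383 with an estimated correlation). Without base replicate 2 the number of hypoxia falls was 2.

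Interferon-stimulated genes rose in 9 of 26 cases and fell in 0, with 14 rises adjusted over the list alone (adjusted p = 1.1e-09; adjusted p = 0.0834 with an estimated correlation). IFI6 rose by 1.52 ± 0.19, IFI27 by 1.18 ± 0.22 and the ubiquitin-like modifier ISG15 by 1.10 ± 0.19. Midpoint replicate 1 had the highest level of all 3, and without it IFI6, IFI27 and ISG15 still passed, with smaller changes of 1.25, 0.80 and 0.80. Cornified envelope genes rose in 6 of 36 cases and fell in 0, or 7 and 1 adjusted over the list alone (adjusted p = 0.00655; adjusted p = 0.0886 with an estimated correlation), with KRTDAP at 1.39 ± 0.26 and IVL at 0.37 ± 0.09. YAP targets rose in 6 of 21 cases and fell in 1, or 6 and 3 adjusted over the list alone (adjusted p = 0.0163; adjusted p = 0.316 with an estimated correlation), with IGFBP3 at 0.79 ± 0.076 and TGFB2 at 0.98 ± 0.10, the latter from below background at base and with other probe sets at -0.131 and -0.053 (adjusted p = 0.777 and 0.914). Luminal markers rose in 7 of 24 cases and fell in 2, or 8 and 2 adjusted over the list alone (adjusted p = 0.0114; adjusted p = 0.0956 with an estimated correlation). ESR1, the estrogen receptor, rose by 0.63 ± 0.092 on its brightest probe set, but the mean of its probe sets gave -0.003 (adjusted p = 0.992), and FOXA1 (0.64 ± 0.15) stayed below background.

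Of the junction lists, 3 of 25 tight junction genes rose and 0 fell, with 6 rises adjusted over the list alone (adjusted p = 0.000852; adjusted p = 0.0643 with an estimated correlation). They were CXADR (0.35 ± 0.093), CLDN7 (0.35 ± 0.092) and TJP1 (0.19 ± 0.05), but other probe sets went the opposite way for TJP1 (-0.185, adjusted p = 0.815) and CXADR (-0.04, adjusted p = 0.963). CLDN4, OCLN, CLDN1 and CDH1 did not pass, with changes of -0.002 ± 0.083, 0.10 ± 0.092, 0.21 ± 0.088 and 0.056 ± 0.058. The kinase MARK2 (0.47 ± 0.094; -0.098 on another probe set, adjusted p = 0.841) and LIN7B (0.35 ± 0.099) were the 2 of 19 polarity genes that rose, with 0 falls and 5 rises adjusted over the list alone (adjusted p = 0.00632; adjusted p = 0.0666 with an estimated correlation). Adherens junction genes had 0 of 11 past the threshold and 2 rises adjusted over the list alone (adjusted p = 0.0179; adjusted p = 0.294 with an estimated correlation). Without base replicate 2 the rises were 5 of the tight junction genes, 3 of the adherens junction genes, 8 of the cornified envelope genes and 8 of the YAP targets. The falls were then 1 of the cornified envelope genes and 2 of the YAP targets, and the NF-kappaB list had 1 rise and 9 falls. KRT14 (-0.71 ± 0.18), KRT18 (-0.44 ± 0.10), MKI67 (-0.53 ± 0.15) and VIM (-0.57 ± 0.13; 0.147 on another probe set, adjusted p = 0.844) fell.

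Several of these calls did not hold with 1 array fewer. Changes without base replicate 3 stayed close to the full ones for TJP1 (0.19), LIN7B (0.34) and CYC1 (-0.26), and leaving out different arrays ended the same calls. LIN7B shrank to 0.27 without midpoint replicate 1. Whether these 3 losses come from fewer samples alone was not tested. Without base replicate 3 the adjusted p was 0.168 for CXADR, 0.181 for CLDN7, 0.107 for TJP1, 0.151 for LIN7B, 0.0966 for FOXA1, 0.132 for IVL, 0.109 for KRT14, 0.091 for KRT18, 0.177 for MKI67 and 0.0655 for VIM. Without base replicate 3 it was also 0.109 for CYC1, 0.0655 for SDHD and UQCRC2 and 0.0986 for ATP5F1A, and for all of these genes but VIM leaving out at least 1 midpoint array also ended the call. DUSP6 did not pass without base replicate 1 (adjusted p = 0.0576) or midpoint replicate 2 (adjusted p = 0.109). Without base replicate 1 the adherens junction (adjusted p = 0.216), YAP (0.164) and luminal (0.0737) lists did not pass, nor did the luminal list without midpoint replicate 1 (0.0543). The other 12 lists did not pass, with adjusted p from 0.0603 to 0.749. The median and mean differed in sign for the adipocyte list. Of these 12, the secreted defence list passed without base replicate 1 (0.027), base replicate 3 (0.0431), midpoint replicate 2 (0.0135) or monolayer replicate 2 (0.0486), the basal list without base replicate 1 (0.0475), and the milk and ER stress lists without base replicate 2 (0.0448 and 0.0263).

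Between base and midpoint 1062 genes changed, 527 higher and 535 lower, and 51 of them by at least 1 (log2), 36 higher and 15 lower. With each array centred on its median the split was 442 higher and 639 lower, and with quantile normalization 520 and 672. The count was 483 without base replicate 3, 580, 600 and 643 without midpoint replicates 1, 2 and 3, and 1454 without base replicate 2, of which 60.6% were higher. It was 3822 with array weights and 600 with only these groups in the model. The 3' minus 5' difference of the dap spike, a measure of labelled length added after the data had been seen, averaged 3.59 at base and 5.17 at midpoint (log2), a gap of 1.57 that was 0.98 without base replicate 2. With it as a covariate the count was 358, while the median absolute change of the 1062 genes went from 0.423 to 0.407 with every sign kept. Their median SE went from 0.0939 to 0.125, so the lower count goes with the larger SE. Over the 4 groups its exact permutation p was 0.0432 (adjusted p = 0.0865). The 18S ribosomal RNA signal, also added then, averaged 10.2 in the monolayer, 9.29 at base, 8.67 at midpoint and 9.58 at plateau (log2; exact permutation p = 0.12). Its midpoint minus base gap of -0.62 was -1.49 without base replicate 2.

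The plateau against midpoint comparison covers the last step along the resistance stages (4 arrays against 3). MMP10 rose by 2.36 ± 0.35 and MMP1 by 2.27 ± 0.41, both enzymes that degrade extracellular matrix. MMP3 and MMP13 rose by 1.29 ± 0.23 and 1.19 ± 0.24 from means below background at midpoint (5.37 and 5.00), so the sizes of these rises are uncertain. SCG5, a chaperone of secretory granules, rose by 1.34 ± 0.19, the adhesion protein gene AMIGO2 by 1.01 ± 0.13 and TAGLN by 0.98 ± 0.14. The epithelial sodium channel subunit SCNN1G fell by 1.06 ± 0.067 on its brightest probe set, while its other probe set gave 0.064 (adjusted p = 0.909) and the mean of them -0.50 (adjusted p = 0.0102).

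The further falls were those of the troponin gene TNNI2 (-0.88 ± 0.11), the transcription factor ZBTB16 (-0.85 ± 0.12), the phosphatidate phosphatase LPIN1 (-0.82 ± 0.10) and ANGPTL4, an inhibitor of lipoprotein lipase (-0.80 ± 0.12). TDRD9, PDK4, which restrains pyruvate oxidation, and SULT1E1, which inactivates estrogens, had changes between -0.79 and -0.76, TDRD9 to a mean below background. The cytokine IL33 passed at 0.92 ± 0.21 but lay below background in every group. The adjusted p of these 16 genes lay between 8.62e-08 and 0.0334. Without midpoint replicate 1 the adjusted p was 0.0689 for MMP1, 0.0659 for MMP3, 0.123 for MMP13 and 0.116 for IL33, and MMP13 did not pass without plateau replicate 2 either (0.0509). IL33 also failed without midpoint replicate 2 (0.154), midpoint replicate 3 (0.115), plateau replicate 1 (0.102), plateau replicate 2 (0.0699) or plateau replicate 4 (0.106).

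NF-kappaB genes rose in 3 of 23 cases and fell in 0, with 5 rises adjusted over the list alone (adjusted p = 0.00158; adjusted p = 0.204 with an estimated correlation). PTGS2 (cyclooxygenase 2) rose by 0.81 ± 0.13, and the chemokines CXCL8 and CXCL2 by 0.98 ± 0.22 and 0.62 ± 0.14. Without midpoint replicate 2 the chemokines did not pass (adjusted p = 0.192 and 0.195), and other single midpoint and plateau arrays also ended their calls. Cornified envelope genes rose in 2 of 36 cases and fell in 0, with 8 rises adjusted over the list alone (adjusted p = 0.000194; adjusted p = 0.0643 with an estimated correlation). The cystatin CST6 rose by 0.39 ± 0.064 and SBSN by 0.81 ± 0.19, the latter not without midpoint replicate 1 (adjusted p = 0.209) or 5 other single arrays. PI3 (0.66 ± 0.088) was the 1 of 15 secreted defence genes that rose, with 0 falls and 2 rises adjusted over the list alone (adjusted p = 0.0367; adjusted p = 0.204 with an estimated correlation). That list did not pass without midpoint replicate 2 (0.207) or plateau replicate 1 (0.113).

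YAP targets rose in 2 of 21 cases and fell in 0, with 3 rises adjusted over the list alone (adjusted p = 0.00733; adjusted p = 0.269 with an estimated correlation). They were CCN1 (0.54 ± 0.12) and IGFBP3 (0.34 ± 0.071), which had adjusted p of 0.118 and 0.124 without midpoint replicate 2, and the list did not pass without plateau replicate 4 (0.0781) or with the replicate number as a block (0.0786). In the EGFR and MAPK list IER3 alone of 23 genes rose (0.41 ± 0.087), with 0 falls and 4 rises adjusted over the list alone (adjusted p = 0.0496; adjusted p = 0.271 with an estimated correlation). That list did not pass without any 1 of 9 arrays, with adjusted p from 0.051 to 0.225, the highest without plateau replicate 4, nor with the replicate number as a block (0.206), and IER3 not without midpoint replicate 2 (0.199). The tight junction list did not pass (adjusted p = 0.14), with 1 rise and 1 fall of 25. The rise was CLDN1 (0.42 ± 0.082), which had adjusted p of 0.0703 and 0.0893 without midpoint replicates 1 and 3. CLDN4, OCLN, TJP1 and CDH1 had changes of -0.03 ± 0.078, 0.012 ± 0.086, 0.059 ± 0.047 and 0.008 ± 0.054, and KRT14, KRT18, VIM, IVL and MKI67 did not pass either (adjusted p from 0.375 to 0.948).

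Hypoxia and glycolysis genes fell in 3 of 23 cases and rose in 0, with 7 falls adjusted over the list alone (adjusted p = 6.17e-05; adjusted p = 0.323 with an estimated correlation). They were ANGPTL4, the vasodilator peptide gene ADM (-0.55 ± 0.11) and DDIT4 (-0.17 ± 0.039), the last pair with adjusted p of 0.116 and 0.123 without midpoint replicate 1. The mitosis list shifted lower with a median of -0.28, although 0 of 30 members passed over all genes and 18 fell adjusted over the list alone (adjusted p = 2.01e-17; adjusted p = 0.12 with an estimated correlation). The replication, p53 and oxidative phosphorylation lists shifted lower too, with medians of -0.061, -0.072 and -0.074 and 0 of 29, 17 and 26 members past the threshold. Adjusted over the list alone, 2, 1 and 0 of them fell. Their adjusted p-values were 0.00148, 0.00985 and 1.11e-05 (adjusted p = 0.458, 0.23 and 0.0643 with an estimated correlation). The replication list did not pass without plateau replicate 3 (0.143), nor the p53 list without midpoint replicate 2 (0.0724) or plateau replicate 1 (0.0582).

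The other 16 lists did not pass, with adjusted p from 0.0516 to 0.925. Of these, the interferon list passed without midpoint replicate 1 (0.00223), the basal list without midpoint replicate 2 (0.0236), the desmosome list without midpoint replicate 3 (0.0226) and the ER stress list without any 1 of 5 arrays, lowest without midpoint replicate 1 (0.023). The list of nuclear-retained RNAs moved with these groups as well, with 3 of 14 members lower, 0 higher and a median of -0.14 (camera p = 2.12e-10; p = 0.000244 with an estimated correlation).

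Between midpoint and plateau 292 genes changed, 134 higher and 158 lower, and 7 of them by at least 1 (log2), 6 higher and 1 lower. Over every probe set the split was 144 higher and 418 lower, and without plateau replicate 3 it was 151 and 87, so it depends on the setting. The count was 81, 74 and 132 without midpoint replicates 1, 2 and 3, and 167 and 165 without plateau replicates 1 and 4. It was 133 with the replicate number as a block, 150 with the mean of a gene's probe sets, 140 without a trend in the prior variance, 784 with array weights and 546 with only these groups in the model.

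**Figure D3:**
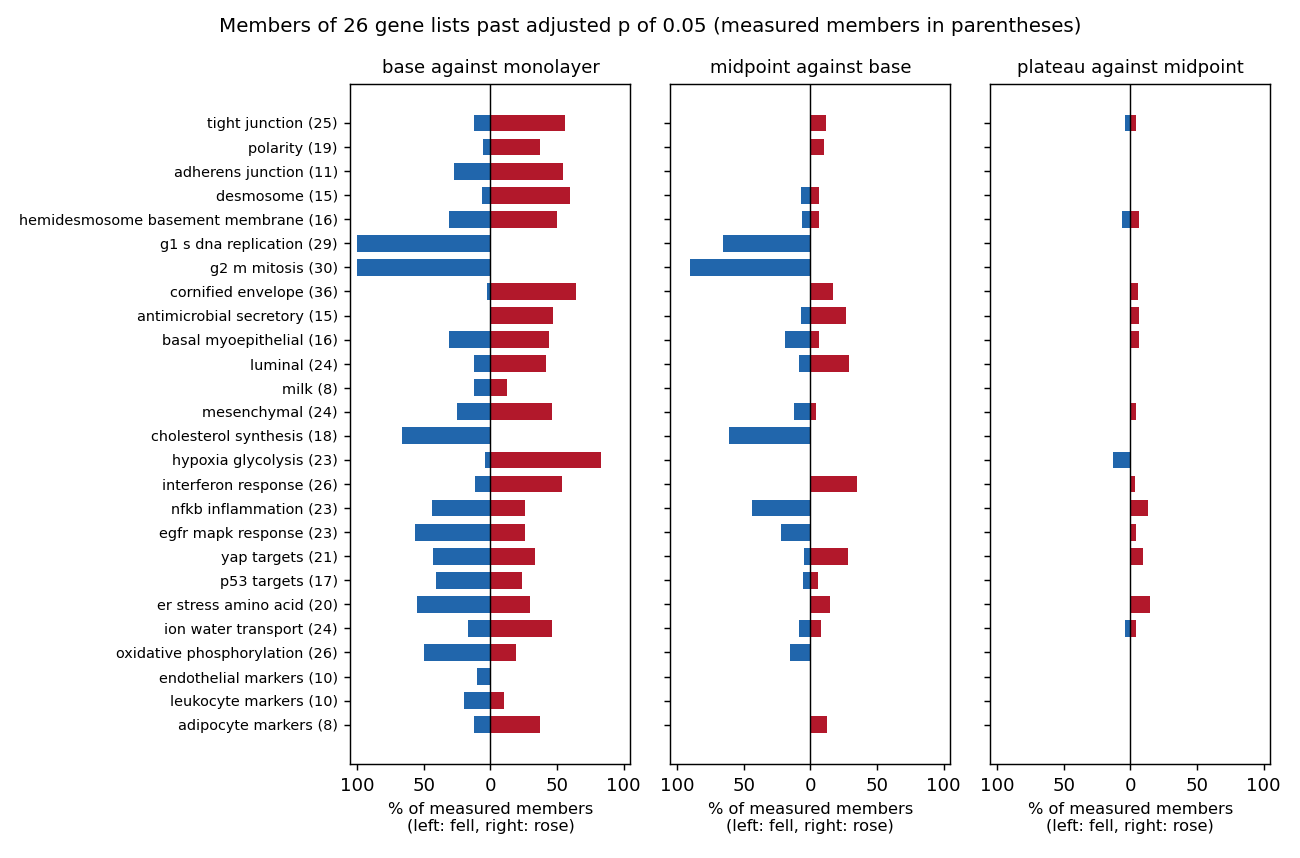
Bars give the percent of the measured members of each of 26 gene lists (number in parentheses) that rose (right, red) or fell (left, blue) at a limma adjusted p under 0.05 in base against monolayer, midpoint against base and plateau against midpoint. All 29 replication and 30 mitosis genes fell in the first panel and 19 and 27 in the second, and 0 of either list passed in the third.

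The plateau against monolayer comparison spans the whole course (4 arrays against 3). Rises included FABP4 (8.45 ± 0.19), KRTDAP (8.42 ± 0.24), OLFM4 (8.15 ± 0.18), GABRP (7.74 ± 0.12) and KRT4 (7.06 ± 0.084). The gap junction protein gene GJA1 rose by 6.84 ± 0.11, the transcriptional inhibitor ID2 by 6.83 ± 0.14 and TCN1 by 6.51 ± 0.16. ETV5 fell by 4.14 ± 0.13, UGT8 by 3.98 ± 0.13, MCM10 by 3.93 ± 0.17 and FBN2 by 3.93 ± 0.12. SPC25, SHCBP1, the meiotic recombination gene MND1 and RRM2 fell too, with changes between -3.89 and -3.62. The adjusted p of these 16 genes lay between 1.89e-21 and 3.01e-13. The monolayer means of the rising genes, between 2.97 and 5.60 (log2), were all below the background level, as were the plateau means of ETV5, UGT8, MCM10, SPC25 and MND1. The sizes and order of these changes therefore rest partly on background signal. So do those of CLDN8, S100A7, CLCA4 and IFIT2 below.

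Tight junction genes rose in 16 of 25 cases and fell in 2, the same adjusted over the list alone (adjusted p = 0.000174; adjusted p = 0.0643 with an estimated correlation), with CLDN8 at 4.36 ± 0.27, CLDN4 at 1.91 ± 0.078, OCLN at 1.83 ± 0.086, CLDN1 at 1.48 ± 0.082 and TJP1 at 0.20 ± 0.047 (-0.018 on its other probe set, adjusted p = 0.959). Desmosome genes rose in 12 of 15 cases and fell in 1, the same adjusted over the list alone (adjusted p = 3.32e-06; adjusted p = 0.0278 with an estimated correlation), with DSC2 at 3.10 ± 0.064. Adherens junction genes rose in 7 of 11 cases and fell in 1, the same adjusted over the list alone (adjusted p = 0.00743; adjusted p = 0.245 with an estimated correlation), with CDH1 at 1.20 ± 0.054. Polarity genes rose in 11 of 19 cases and fell in 1, or 11 and 2 adjusted over the list alone (adjusted p = 0.0117; adjusted p = 0.0831 with an estimated correlation), with PARD6G at 1.45 ± 0.076 and PRKCZ at 0.93 ± 0.076. PARD3B rose by 0.69 ± 0.10 on its brightest probe set, but another of its probe sets fell by 0.309 (adjusted p = 0.0198), so its direction stays open.

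Cornified envelope genes rose in 28 of 36 cases and fell in 0, or 29 and 0 adjusted over the list alone (adjusted p = 2e-14; adjusted p = 0.00588 with an estimated correlation), with KRT13 at 6.27 ± 0.072, S100A7 at 5.74 ± 0.20 and IVL at 3.56 ± 0.084. Secreted defence genes rose in 8 of 15 cases and fell in 0, also adjusted over the list alone (adjusted p = 0.000105; adjusted p = 0.0643 with an estimated correlation), with LCN2 at 4.76 ± 0.14 and SLPI at 2.65 ± 0.039. Luminal markers rose in 10 of 24 cases and fell in 3, the same adjusted over the list alone (adjusted p = 0.00298; adjusted p = 0.0666 with an estimated correlation), with MUC1 at 3.51 ± 0.077, while KRT18 fell by 1.68 ± 0.095. KRT14 rose by 3.06 ± 0.17 and VIM fell by 0.67 ± 0.12. Ion and water transport genes rose in 13 of 24 cases and fell in 5, the same adjusted over the list alone (adjusted p = 0.0203; adjusted p = 0.0831 with an estimated correlation), with CLCA4 at 5.80 ± 0.26. Interferon-stimulated genes rose in 18 of 26 cases and fell in 1, or 19 and 1 adjusted over the list alone (adjusted p = 2.5e-06; adjusted p = 0.165 with an estimated correlation), with IFIT2 at 2.52 ± 0.12. Hypoxia and glycolysis genes rose in 18 of 23 cases and fell in 4, the same adjusted over the list alone (adjusted p = 0.000106; adjusted p = 0.334 with an estimated correlation), with the glucose transporter SLC2A1 at 1.85 ± 0.075 and ANGPTL4 at -1.75 ± 0.12.

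All 29 replication and 30 mitosis genes fell, also adjusted over the list alone, with medians of -2.29 and -2.68 (adjusted p = 6.05e-24 and 3.18e-25; adjusted p = 0.0643 and 0.0727 with an estimated correlation). MKI67 fell by 2.78 ± 0.14, CDC20 by 3.57 ± 0.17 and BIRC5 (survivin) by 3.15 ± 0.16. Cholesterol synthesis genes fell in 16 of 18 cases and rose in 1, the same adjusted over the list alone (adjusted p = 1.42e-07; adjusted p = 0.165 with an estimated correlation), with DHCR7, of the final step, at -1.90 ± 0.13. EGFR and MAPK genes fell in 15 of 23 cases and rose in 6, the same adjusted over the list alone (adjusted p = 0.00314; adjusted p = 0.123 with an estimated correlation), with FOSL1 at -2.25 ± 0.10. Oxidative phosphorylation genes fell in 18 of 26 cases and rose in 1, or 19 and 3 adjusted over the list alone (adjusted p = 4.78e-05; adjusted p = 0.0643 with an estimated correlation), with CYC1 at -0.95 ± 0.065. The other 11 lists did not pass, with adjusted p from 0.105 to 0.902. The median, mean or test differed in sign for the hemidesmosome, milk and NF-kappaB lists. The list of nuclear-retained RNAs chosen after the data had been seen moved with these groups too, with 10 of 14 members higher, 0 lower and a median of 0.44. Its camera p was 0.000585, or 0.0115 with an estimated correlation.

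Between monolayer and plateau 9077 genes changed, 4676 higher and 4401 lower, and 2083 of them by at least 1 (log2), 1120 higher and 963 lower. Midpoint against monolayer gave 8775 genes, 4520 higher and 4255 lower, with 15 lists past the threshold, and plateau against base gave 2761, 1443 higher and 1318 lower, with 16 lists. With each array centred on its median the splits were 3523 higher and 6397 lower, 3536 and 6414, and 1132 and 1661. Over the 6 comparisons 84 of 156 list tests passed, and 9 with an estimated correlation. The plateau against base count was 4574 with array weights and 1824 with only these groups in the model.

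The changes of the first step (base minus monolayer) were compared with those of the last (plateau minus midpoint), which share no array. Across 19775 genes, which are not independent replicates, their Pearson correlation was 0.0243 and their Spearman correlation 0.0113. Among genes changed in both steps, 61 rose in both (27.1 for independent lists), 113 rose and then fell (32), 45 fell and then rose (28.4) and 24 fell in both (33.5). AMIGO2 fell by 2.59 in the first step and rose by 1.01 in the last, and ANGPTL4 fell in both, by 0.57 and 0.80.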

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

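The values of 103 named genes and 4 quality measures were searched for single arrays far from the rest of their group, which was possible only at plateau, the 1 group with 4 arrays. An array was flagged by Dixon's ratio of its gap to the range of the group. The limit was not adjusted for the number of genes searched, so some flags can arise by chance. In 3 genes 1 plateau array lay apart: IFI44 at 7.344 in plateau replicate 4 (others 7.201 to 7.218), NDUFS1 at 9.224 in plateau replicate 3 (others 9.459 to 9.503) and OCLN at 10.01 in plateau replicate 1 (others 10.044 to 10.051), all log2. The gaps of IFI44 and OCLN were small beside the plateau against monolayer changes of these genes. NDUFS1 lay at 10.076 to 10.23 in the monolayer arrays, so its gap was a larger part of its change. The calls of OCLN, IFI44 and NDUFS1 in plateau against monolayer held without any 1 array.

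Probe sets that carry no gene name here, or several, were not tested as genes. Of those with no name, control probe sets left out, 255 of 11721 were at least 2-fold higher at plateau than in the monolayer and 169 at least 2-fold lower. Of those with several genes, 78 of 1801 were at least 2-fold higher and 69 at least 2-fold lower. These counts also required an adjusted p under 0.05 over every probe set. What these probe sets measure was not analysed here.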

How the results depend on the processing

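Of 257 results for named genes 242 passed, 195 of them in every setting tried on named genes other than single probe sets, and 37 did not pass without some 1 array. Quantile normalization and the ACTB and spike covariates were not tried on named genes. The filter at the median gene kept 222 of the 257 results. Quantile normalization moved no count by more than 1.5 times. With fewer tests, a fold limit or another unit counted, numbers moved by construction. Testing every probe set gave 17622, 19567 and 19853 probe sets for base, midpoint and plateau against monolayer, 562 (144 higher and 418 lower) for plateau against midpoint and 4173 for plateau against base. A change of at least 1 (log2) left 1650, 2052 and 2083 genes against the monolayer, 51 for midpoint against base, 7 for plateau against midpoint and 139 for plateau against base. Array weights gave 3822 genes for midpoint against base, 784 for plateau against midpoint and 4574 for plateau against base, and fitting only the 2 groups gave 600, 546 and 1824. The spike covariate, chosen after the data had been seen, left 358 for midpoint against base, with the median change of the 1062 genes at 0.407 against 0.423 and a larger SE. For plateau against midpoint, the mean of a gene's probe sets gave 150 and a prior variance without trend 140, and the cause was not tested.

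The replicate number as a block gave 8056, 8660, 8630, 919, 133 and 2200 genes, and ended the list calls of EGFR and MAPK genes (adjusted p = 0.206) and YAP targets (adjusted p = 0.0786) in plateau against midpoint. After the group mean of each gene was subtracted, the deviations of the 18 same-number pairs correlated at -0.222 to 0.177, 1 of them over 0.1. Of 12 arrays, 2 correlated best with their own number. By this measure the deviations of same-number arrays had little in common. With the correlation between genes estimated, 9 list tests passed of 84, with 2 for each comparison against the monolayer, 1 for midpoint against base, 0 for plateau against midpoint and 2 for plateau against base. The fry test called 100 in all but 5 for plateau against midpoint. It put the NF-kappaB list higher at plateau than in the monolayer (median 0.0853, fry adjusted p = 0.0205), opposite in direction to camera. Fry and camera test different hypotheses, and the cause was not tested further.

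Leaving out 1 array gave 7570 to 8172 genes for base against monolayer, 8109 to 8281 for midpoint against monolayer, 8437 to 8906 for plateau against monolayer, 483 to 1454 for midpoint against base, 74 to 238 for plateau against midpoint and 2000 to 3109 for plateau against base. List calls ranged from 82 to 88 in all, and by comparison in the same order 13 to 15, 15 to 15, 15 to 15, 13 to 16, 8 to 12 and 15 to 18. The correlation of the first and last step ranged from -0.0135 to 0.0594, the ACTB range from 0.0466 to 0.416 and the GAPDH range from 0.158 to 0.311, the last without monolayer replicate 3 (exact permutation p = 0.0138). Fewer samples can lower the counts. For midpoint against base, however, leaving out base replicates 1, 2 and 3 gave 1370, 1454 and 483 genes with the same number of arrays. The cause of these differences was not tested.

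Other probe sets of a gene gave the opposite sign in these cases (log2). In base against monolayer these were COL8A1 0.061 and NDUFS1 0.234. In midpoint against base they were SERPINA1 0.145, FBN2 0.068, CXADR -0.04, TJP1 -0.185, MARK2 -0.098, GINS2 0.074, CCNB2 0.01 and 0.003, SPRED2 0.001, TGFB2 -0.131 and -0.053, ATP5F1A 0.05 and VIM 0.147, and for ESR1 -0.12, -0.065, -0.028, -0.139, -0.077, -0.225 and -0.035, with -0.003 for the mean of its probe sets. In plateau against midpoint it was SCNN1G 0.064, and in plateau against monolayer PARD3B -0.016 and -0.309 and TJP1 -0.018. The cause was not tested. Signal over background limits genes under the background level of 6.17: 731, 875 and 950 changed genes against the monolayer, 40 in midpoint against base, 25 in plateau against midpoint and 182 in plateau against base lay near it. A linear-scale alternative did not apply, as the values are log2.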

Other observations

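Gene families were searched after the data had been seen, and 78 of 1368 tests of 342 families passed, 0 of them with an estimated correlation (adjusted p = 0.688 for each of those named here). The mitochondrial ribosomal MRPL genes fell in 48 of 50 cases and rose in 1 at plateau against monolayer (median -0.682, adjusted p = 6.02e-16). Metallothionein (MT) genes fell in 7 of 10 cases from base to midpoint (median -0.325, adjusted p = 4.89e-12), with MT1F at -0.45 and MT2A at -0.29. Among the KLF factors 11 of 19 rose and 1 fell at base against monolayer (median 0.698, adjusted p = 0.00207), and of the clade B serpins 6 of 12 rose and 1 fell (adjusted p = 0.00975), with SERPINB13 at 4.14. The protocadherin PCDHB genes rose in 12 of 17 cases and fell in 0 at plateau against monolayer (adjusted p = 0.00214). The MMP genes rose in 5 of 24 cases and fell in 0 from midpoint to plateau (adjusted p = 0.0381), with a median of 0.0109.

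In the tests below, the spike covariate, the midpoint array test, the rule on the share of list members with the same sign and the rule that sets aside a covariate alike in both groups were chosen after the result had been seen.

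The genes changed between base and midpoint could be due to 1 odd array or to labelled length. Without base replicate 2, 869 of 1062 stayed changed, which argues against that array as the cause. By the same measure 914 stayed without base replicate 1 and 560, 594 and 610 without midpoint replicates 1, 2 and 3. Without base replicate 3, 477 stayed, which falls short of the bar set beforehand for base replicate 2. A part for base replicate 3 therefore stays open. With the ACTB 3' minus 5' difference as a covariate 1062 stayed changed. That difference averaged 1.39 at base (1.78 without base replicate 2) and 1.41 at midpoint (log2), so it could not have moved these changes and decides nothing. With the spike difference as a covariate 328 stayed, yet all 1062 kept their sign, with a median absolute change of 0.407 against 0.423 and a median SE of 0.125 against 0.0939. The lost calls came with the larger SE, so labelled length stays open beside the stage.

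The 158 genes lower at plateau than at midpoint might reflect labelled length, a smaller share of nuclear-retained RNA or a weaker glucocorticoid response. With the spike covariate 114 stayed lower, which met the bar for staying, and the median absolute change was 0.421 against 0.413. The spike gap was only -0.696 (log2, plateau minus midpoint; exact permutation p = 0.2), so the covariate had little difference to remove. Labelled length therefore stays open here too. The nuclear-retained list had a median of -0.144 with 13 of 14 members negative and 3 lower, which met the test for the second. The list was chosen after the data had been seen, and its 3 lower members are themselves among the 158. It therefore cannot decide the question. MALAT1 went the other way (0.138 ± 0.387), and the share of nuclear RNA itself was not measured. The glucocorticoid list had a median of -0.108, with FKBP5 and TSC22D3 lower (p = 0.0246; p = 0.04 with an estimated correlation), which met the test set beforehand, but 8 of 15 members were negative and the others positive, so it stays open. This list was also lower at midpoint than at base (11 of 15 negative, 5 fell, p = 0.000261; p = 0.00363 with an estimated correlation) and at plateau than at base (8 fell, p = 2.53e-05), but higher at base than in the monolayer (median 0.421, 8 rose, 2 fell, p = 0.000663; p = 0.00544 with an estimated correlation) and at midpoint than in the monolayer (p = 0.0185).

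The 8 largest rises from midpoint to plateau could come from 1 array, from a TGF-beta response or from an SRF and contractile response. Of the 8 genes, 2 did not pass without some 1 plateau array, within the limit set beforehand. All 8 had been picked with every plateau array above every midpoint array. A rise carried by 1 plateau array could hardly enter, so this test cannot decide the question for plateau arrays. Leaving out 1 midpoint array gave a lowest median of 1.13 against 1.24. The 8 genes were picked as large rises in these same arrays, so a steady median cannot decide the question for midpoint arrays. MMP1, MMP3, MMP13 and IL33 did not pass without midpoint replicate 1, so a part for that array stays open. TGF-beta targets not named above had a median of 0.171 with 13 of 18 positive and 3 higher (p = 0.000208; p = 0.0842 with an estimated correlation). That met the test set beforehand, but only at the preset correlation. The SRF and contractile list had a median of 0.0843 with 14 of 17 positive and TPM1 higher (p = 0.000872; p = 0.0209 with an estimated correlation), which met its test. Of the genes of these lists, 7 and 5 also stand in lists used above. Both lists were chosen after the data had been seen, so they cannot decide the cause of the rises. Neither was tested against the stage itself, and a change of culture age remains possible.

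Arrays were also regrouped, and the number of groupings with at least the real count, the real grouping included, is given with the real count and the highest other. For genes changed it was 1 of 10 for base against monolayer (8194, highest other 0), 1 of 10 for midpoint against monolayer (8775, 0), 1 of 35 for plateau against monolayer (9077, 5507), 1 of 10 for midpoint against base (1062, 9), 1 of 35 for plateau against midpoint (292, 38), 1 of 35 for plateau against base (2761, 417) and 1 of 100 for the F test (9222, 3857). For lists it was 1 of 10 for base against monolayer (14, 9), 1 of 10 for midpoint against monolayer (15, 12), 2 of 35 for plateau against monolayer (15, 15), 1 of 10 for midpoint against base (14, 11), 2 of 35 for plateau against midpoint (10, 11) and 1 of 35 for plateau against base (16, 15). With 10 groupings the share of groupings cannot fall under 0.05, and chance was not excluded for the numbers of lists in plateau against monolayer and plateau against midpoint.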
